A study of Mus musculus with 2 samples.

How the data were processed

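Immune cells from tumours of mice inoculated with MC38 cells were measured by droplet-based single-cell RNA sequencing (10x) on day 14. The series holds 2 libraries, 1 from wild-type mice (WT) and 1 from mice with the Ifnar1-SA genotype, and each was placed in its group by the genotype in the labels. How many animals went into each library, and whether the cells were sorted before loading, is not given in the sources used here.

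The deposited values are raw UMI counts (unique molecular identifiers, each standing for 1 captured transcript) per gene and barcode, made by the authors with Cell Ranger 4, per the file headers. The genome build was mm10, per the submitters' processing notes. The annotation release and alignment settings are not given in the sources used here. Both deposited count matrices list 6794880 barcodes and 32285 genes and had not been filtered for cells, since 1082422 barcodes in WT and 1258828 in Ifnar1-SA carried at least 1 UMI. The depth was 55497066 UMIs in WT and 62732220 in Ifnar1-SA.

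The cell filters, clustering settings, gene lists, cell type markers, rule for named genes and 16 alternatives were chosen before the data were examined. A barcode was kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. The minimum of 1000 UMIs was passed by 4600 barcodes in WT and 5880 in Ifnar1-SA, which held 88.6% and 88.7% of all UMIs. The gene minimum then removed 167 and 314 barcodes and the mitochondrial maximum 375 and 565. Scrublet's scoring, run per library, set an automatic limit that marked 0% and 0.0400% of cells, so the planned fallback was used: the top scores were removed at 0.8% per 1000 cells, or 132 WT and 200 Ifnar1-SA barcodes. Since 36 and 56 barcodes shared the score at that limit and all of them were removed, 162 and 213 barcodes were taken out, which is more than the rule allowed. There remained 3896 WT and 4788 Ifnar1-SA cells, with medians of 7620 and 6848 UMIs and 2199 and 2096 genes.

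Counts were scaled to 10000 per cell and log-transformed, and cells of both libraries were clustered together without batch integration, with scanpy 1.11.5 under Python 3.11.15. The clustering used 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. Members of the fixed interferon gene lists and sex-linked, mitochondrial, ribosomal and antigen receptor segment genes were left out of the variable genes, so that clusters could not form on them. Interferon-inducible genes outside those lists, such as Ch25h and Slfn4, could still enter, so clusters may in part follow interferon response. Clusters were named from the fixed markers. The marker levels a cluster had to reach were set after the clusters were seen, so the share of cells that stayed outside every class is given beside the class shares. A cluster was kept out as mixed when most of its cells held at least 3 UMIs of T cell markers together with at least 20 of macrophage markers.

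Within each class UMIs were summed per library and expressed as CPM, counts scaled to 1 common total. The log2 ratio of Ifnar1-SA over WT has a 95% interval from the exact conditional binomial for a pair of Poisson counts, and shares of cells have exact Clopper-Pearson intervals. All of these intervals cover counting error only. With 1 library per group there is no spread between replicates, so no test between genotypes was made and no p-value is given, and every difference compares these libraries and has no replicate check. The classes compared had at least 100 cells in each library.

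The fixed lists were type I interferon, interferon gamma leaning, interferon receptors and signalling, cytotoxic effector, inhibitory receptor and exhaustion, naive, stem and memory, tissue residency, proliferation, survival and apoptosis, MHC class I and MHC class II presentation, costimulation and checkpoint ligands, alternatively activated and suppressive macrophage, inflammatory myeloid, regulatory T function, hypoxia and glycolysis, sterol, dissociation stress, red cell RNA and sex-linked genes. A member entered a list's median with a mean of at least 20 CPM over both libraries in that class. The median is given with its percentile among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Mx1 and Mx2, which belong to the type I interferon list, were not analysed here. Genes were named when they reached 50 CPM in either library and 30 UMIs over both, with an interval wholly outside 1.5-fold. The 12 highest and 12 lowest were taken in CD8 T-like cells and the 5 highest and 5 lowest in other classes. Mitochondrial, ribosomal, antigen receptor, sex-linked and predicted genes were left out of that ranking. Ifnar1, Ifnar2, Ch25h and the most abundant list members were given in addition.

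Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs, leaving out shallower cells. Members of near-identical gene families, such as the histone, granzyme, Ly6, Ms4a4 and Slfn genes, can share reads that the authors' counting may have split, so their values are uncertain. Coordinates come from the GENCODE M21 annotation of GRCm38, the assembly called mm10, whose gene identifiers matched those of the files for every gene given here.

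The summing and list steps were tested on simulated Poisson counts of 5422 genes, with the profile of the whole WT library and the depth of the CD8 T-like sums. Poisson counts meet the assumption of the intervals by design, so the coverage does not show how they hold when UMIs clump in few cells. The intervals held the true ratio for 95.4% of genes, 95.5% of 132 eligible genes changed 2-fold were named, and 0 unchanged genes were named. A list raised 2-fold gave a median of 1.02 at percentile 100. Of lists drawn at random, which could include changed genes, 8% fell outside the central 95%. The 16 alternatives changed the UMI minimum, alone or together with the gene minimum, the mitochondrial maximum, doublet removal, cluster resolution, gating, scaling, weighting of cells, depth, free RNA and expression filter. A further 6 alternatives, on cells with markers of another lineage, sex-linked transcripts, the make-up of classes and tied doublet scores, were chosen after seeing the data.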

Results

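Tumour-infiltrating immune cells were profiled by droplet-based single-cell RNA sequencing from mice that carried tumours of MC38, a mouse colon adenocarcinoma line, on day 14. The data comprise 1 library of wild-type mice (WT) and 1 library of mice with the Ifnar1-SA genotype, named for an allele of Ifnar1, which encodes a chain of the type I interferon receptor. The labels describe the cells both as infiltrating immune cells and as CD8 T cells. They do not say what SA stands for. The comparison asks how tumour-infiltrating immune cells differ between the genotypes. After filtering, 3896 WT cells with a median of 7620 UMIs and 4788 Ifnar1-SA cells with a median of 6848 UMIs remained. Since each genotype is 1 library, "higher" and "lower" describe these libraries, intervals cover counting error only, and no difference below has a replicate check.

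Ifnar1 transcripts (ENSMUSG00000022967, chromosome 16, 91485238 to 91507441 on the plus strand of mm10, protein-coding) were present in every class compared. In CD8 T-like cells Ifnar1 stood at 70.0 CPM in WT (538 UMIs) and 81.1 CPM in Ifnar1-SA (333 UMIs), a log2 ratio of 0.21 (95% interval 0.01 to 0.41). The ratio was 0.21 in regulatory T-like cells, 0.21 in other T-like cells and 0.09 in monocyte/macrophage-like cells. Counts of the transcript's 3' end do not show which allele a cell carries, so they do not check the genotype labels. Ifnar2, the partner chain of the receptor, had log2 ratios of -0.31 (-0.66 to 0.02) in CD8 T-like cells and -0.02 (-0.09 to 0.04) in monocyte/macrophage-like cells. Ch25h, which encodes cholesterol 25-hydroxylase and is an interferon-inducible gene, was measured mainly in monocyte/macrophage-like cells, at 121.0 CPM in WT and 124.1 CPM in Ifnar1-SA.

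CD8 T-like cells, defined by Cd3 and Cd8 transcripts, made up a smaller part of the Ifnar1-SA library, and regulatory T-like cells, defined by Foxp3, a larger part. CD8 T-like cells were 25.5% of kept cells in WT (24.2 to 26.9%, 994 cells) and 13.5% in Ifnar1-SA (12.5 to 14.4%, 644 cells). Regulatory T-like cells were 13.8% (12.77 to 14.96%) and 16.9% (15.8 to 17.9%). Among the T cells of these named classes, CD8 T-like cells were 53.3% in WT and 35.3% in Ifnar1-SA, and there were 1.84 and 0.798 CD8 T-like cells per regulatory T-like cell. Monocyte/macrophage-like cells, with C1qa, Lyz2 and Csf1r, were 39.1% in WT (37.6 to 40.6%) and 42.8% in Ifnar1-SA (41.4 to 44.2%). Other T-like cells, whose leading genes include Il2, Gzma and Cd40lg, were 8.55% and 7.79%. Dendritic cell-like, migratory dendritic cell-like, plasmacytoid dendritic cell-like, endothelial-like and fibroblast-like cells each stayed below 2% in both libraries. Clusters kept out of all classes held 8.68% of WT and 15.2% of Ifnar1-SA cells.

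**Figure D1:**
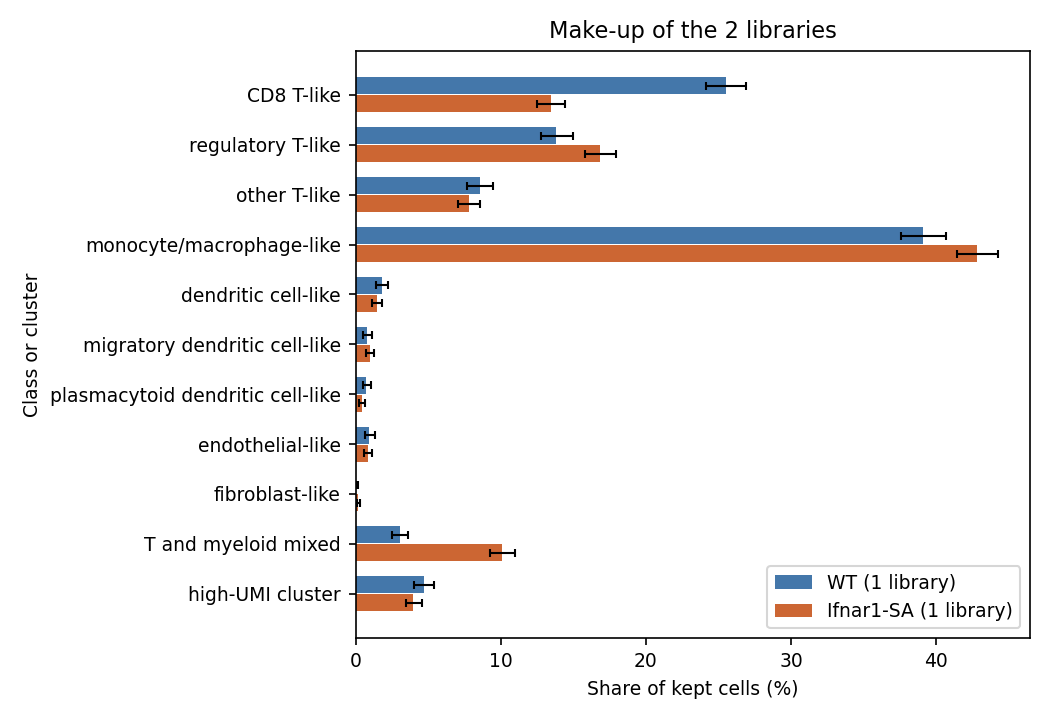
Share of kept cells (%, horizontal axis) in each class or cluster, for the WT library (blue) and the Ifnar1-SA library (orange), with exact 95% binomial intervals that cover counting error only. CD8 T-like cells are at 25.5% in WT and 13.5% in Ifnar1-SA, and the mixed T and myeloid cluster at 3.03% and 10.1%.

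The labels name no sort that would set these shares. The difference in CD8 T-like share was -12.1 points, and it was -5.84 points with a marker gate on single cells in place of clusters. With a higher UMI minimum, 8030.0 in WT and 7951 in Ifnar1-SA, which removed many T cells, the regulatory T-like share was lower in Ifnar1-SA by -0.56 points and the monocyte/macrophage-like share by -2.76 points. Both also turned in splits by sex-linked transcripts: the regulatory T-like difference was -5.26 points when Ifnar1-SA cells with Y-linked transcripts only were set against WT, and the monocyte/macrophage-like difference was -1.16 points among cells with Xist only.

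Sex-linked transcripts differed between the libraries. Xist, transcribed from the inactive X chromosome, had 42647 UMIs in WT and 35418 in Ifnar1-SA. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 4 UMIs in WT and 1226 in Ifnar1-SA. There, 525 cells held Y-linked UMIs without Xist, 3198 held Xist without Y-linked UMIs, 215 held both and 850 neither. Cells with neither were 93 of 644 CD8 T-like and 363 of 2050 monocyte/macrophage-like cells in Ifnar1-SA, against 28 of 994 and 31 of 1523 in WT. Among Ifnar1-SA cells with either kind alone, the Y-linked part was 24.1% of CD8 T-like (20.6 to 27.9%), 6.16% of regulatory T-like (4.53 to 8.16%), 9.48% of other T-like and 17.5% of monocyte/macrophage-like cells. CD8 T-like cells per regulatory T-like cell were 0.606 (0.535 to 0.685) among Ifnar1-SA cells with Xist only and 2.93 (2.08 to 4.21) among those with Y-linked transcripts only, against 1.84 (1.66 to 2.05) in WT. The CD8 T-like share was 25.1% among the Y-linked Ifnar1-SA cells, -0.37 points from WT, and -14.2 points from WT when Xist-only cells of both libraries were compared. These splits were made after the data were seen. Since Y-linked transcripts can be missed in cells that carry them, the Y-linked parts may be too low. Cells in which they were found may also be the deeper ones, which was not corrected for in these shares.

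**Figure D2:**
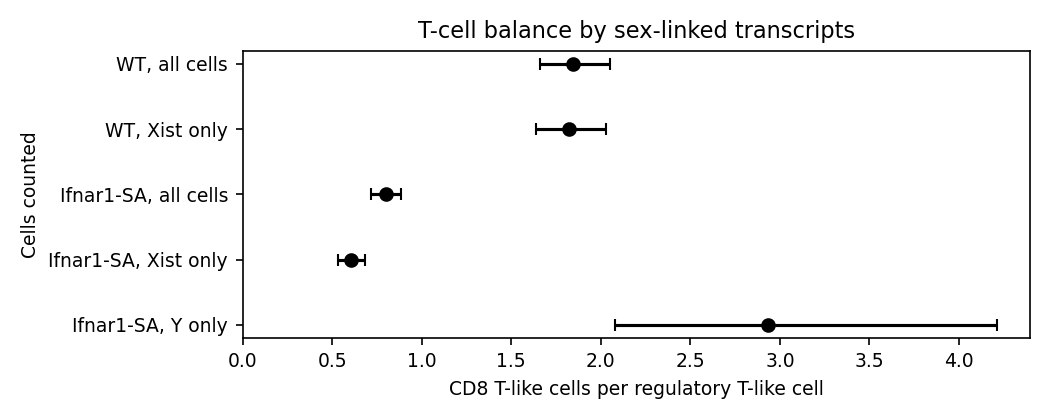
CD8 T-like cells per regulatory T-like cell (horizontal axis, ratio of cell counts) for all cells and for cells split by sex-linked transcripts, with exact 95% intervals that cover counting error only. Ifnar1-SA cells with Xist only lie at 0.606 and those with Y-linked transcripts only at 2.93, with WT between them at 1.84.

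A cluster in which most droplets carried T cell transcripts such as Cd3e and Trac together with macrophage transcripts such as C1qa and Apoe held 3.03% of WT cells (2.51 to 3.62%) and 10.1% of Ifnar1-SA cells (9.27 to 11.0%). It was kept out of the T and myeloid classes. Its droplets had medians of 14855 UMIs in WT and 12582.5 in Ifnar1-SA, above those of the library as a whole. In Ifnar1-SA, 15.8% of its droplets with sex-linked transcripts held both Xist and a Y-linked gene (12.6 to 19.4%), compared with 6.28% in monocyte/macrophage-like cells (5.17 to 7.55%).

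Most genes of the type I interferon list were higher in Ifnar1-SA in the T classes and in monocyte/macrophage-like cells. Irf7, a transcription factor that amplifies interferon production, had log2 ratios of 1.70 (1.52 to 1.88) in regulatory T-like, 1.41 (1.12 to 1.71) in other T-like, 0.59 (0.35 to 0.82) in CD8 T-like and 0.56 (0.52 to 0.60) in monocyte/macrophage-like cells. Isg15, a ubiquitin-like modifier, was at 310.0 CPM in WT and 707.1 CPM in Ifnar1-SA in regulatory T-like cells, and Rsad2, the antiviral enzyme viperin, at 16.2 and 69.4 CPM there. In regulatory T-like cells 47 of 47 measured list members were higher, with a median log2 ratio of 0.76. In other T-like cells 48 of 49 were higher, with a median of 0.58, and in monocyte/macrophage-like cells 50 of 52, with a median of 0.38. In CD8 T-like cells 31 of 38 were higher and the median was 0.20. Each of these medians lay above all 10000 random lists matched on expression (percentile 100), whose central 95% ran from -0.08 to 0.08 in CD8 T-like cells and from 0.01 to 0.09 in monocyte/macrophage-like cells. The CD8 T-like median was 0.36 with Leiden resolution 2 and with clusters weighted equally, and 0.39 with the marker gate. It was 0.38 with a mitochondrial maximum of 5% and 0.38 with the higher UMI minimum. With a minimum of 2000 UMIs together with a raised gene minimum it was 0.14. It was 0.17 with a mitochondrial maximum of 20% and 0.17 among cells with Xist only. The other T-like median was 0.36 with cells thinned to 1 depth and 0.32 when only Y-linked Ifnar1-SA cells were set against WT.

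**Figure D3:**
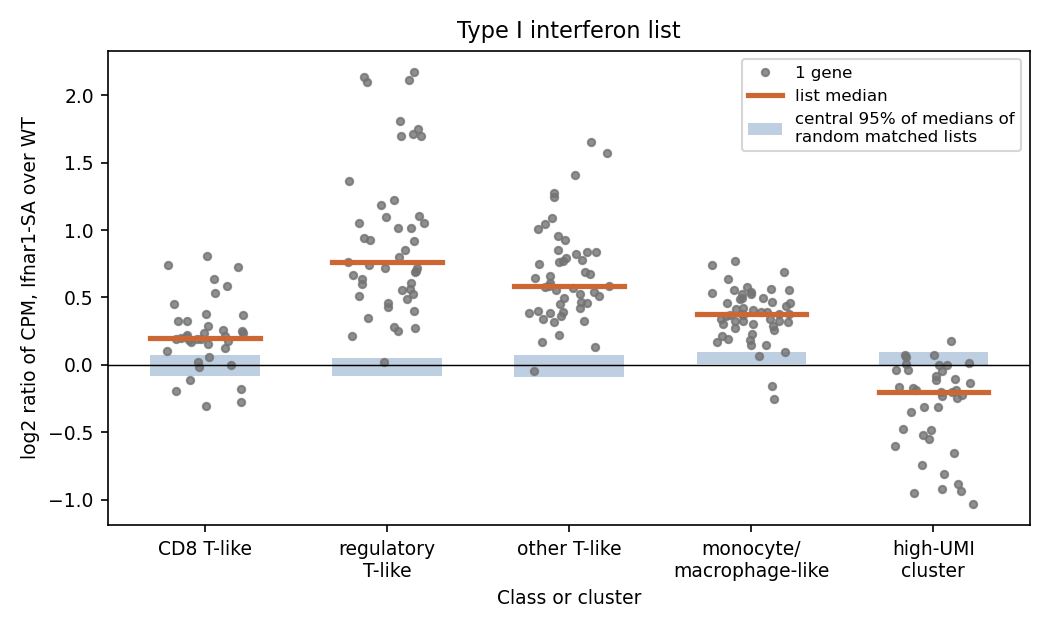
Log2 ratio of CPM (Ifnar1-SA over WT, vertical axis) of the type I interferon list in each class or cluster. Grey points are genes, orange bars list medians and blue bands the central 95% of medians of random matched lists; medians run from 0.76 in regulatory T-like cells to -0.20 in the high-UMI cluster.

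In CD8 T-like cells most cytotoxic effector genes, among them Ifng, Ccl3 and Gzmb but not Gzmk, were higher in Ifnar1-SA, and proliferation genes and the integrin gene Itga4 were lower. Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), the gene for interferon gamma, stood at 325.0 CPM in WT and 1050 CPM in Ifnar1-SA, a log2 ratio of 1.69 (1.62 to 1.76). The T cell chemokine gene Ccl3 had a log2 ratio of 1.55 (1.48 to 1.62) and Xcl1, which attracts cross-presenting dendritic cells, 0.77 (0.73 to 0.82), and Ccl4 was at 1371 CPM in WT and 2741 CPM in Ifnar1-SA. Gzmb, a granzyme that triggers apoptosis in target cells, was at 1073 CPM in WT and 1414 CPM in Ifnar1-SA. Itga4 (ENSMUSG00000027009, chromosome 2, 79255426 to 79333123), the alpha 4 integrin chain used in binding vessel walls, was at 135.8 CPM in WT and 36.5 CPM in Ifnar1-SA, a log2 ratio of -1.89 (-2.15 to -1.65).

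The CD8 T-like class drew on clusters in unequal parts. Cluster 11, led by Gzmf, Cd8a and Klrd1, held 57.9% of the class in WT and 38.5% in Ifnar1-SA. Cluster 7, whose leading genes include Xcl1, Ifng, Ccl3, Crtam and Gpm6b, held 15.9% and 44.1%, and cluster 12, led by Gzmc, Gzmf and Prf1, 26.2% and 17.4%. Since leading genes of cluster 7 such as Ifng and Ccl3 themselves differ between the libraries, these shares give the make-up of the class and are not read as a difference in cell states. Within clusters 7, 11 and 12 the Ifng log2 ratio was 1.14, 0.54 and 0.42, that of Ccl3 was 1.16, 0.45 and -0.49, and that of Itga4 was -1.68, -2.13 and -1.43. That of Areg was 1.89, -0.22 and 1.41, and that of Bcl2 was -0.017 (-0.41 to 0.38), -1.03 and -0.73. The type I interferon median within them was 0.52, 0.36 and 0.32. With the clusters weighted equally the log2 ratio was 0.96 for Ifng, 0.86 for Ccl3 and 0.36 for Crtam. Cells clustered again within the class fell into states led by Bdh2 and Dapl1, by Il2 and Gzma, by Ifit3 and Itga1, and by Styk1 and Osgin1. Others were led by the mast cell genes Mcpt4, Cpa3 and Cma1 ahead of Gzmc and Gzme, by the mitotic genes Ube2c and Cenpf, and by Cxcl9 and macrophage genes such as C1qa. The Bdh2 and Dapl1 state held 10.6% of the class in WT and 24.8% in Ifnar1-SA, and the Il2 and Gzma state 6.34% and 17.1%. The mitotic state held 19.1% and 11.8%, and every remaining state was also smaller in Ifnar1-SA. Leading genes of the larger states, such as Gpm6b, Ms4a4c, Il2 and Ccl3, are also among the named genes below. Make-up of the class and expression within cells were therefore not separated.

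By the rule for named genes, the 12 highest in CD8 T-like cells were Il2, Penk, Ifng, Areg, Ccl3, Gzme, Ms4a4c, Gzmd, Lgals3, Cd9, Gpm6b and Crtam. Penk, the proenkephalin gene, had a log2 ratio of 2.24 (1.90 to 2.59), Lgals3, the gene for galectin-3, 1.43, and Crtam, an adhesion receptor of activated T cells, 1.29 (1.06 to 1.52). Il2, the T cell growth factor gene, had 3.21 (2.83 to 3.61), but its UMIs came from 15 WT and 20 Ifnar1-SA cells, and 5 cells held 85.3% and 83.0% of them. Its ratio turned to -0.47 with minimums of 2000 UMIs and 800 genes per cell and to -2.84 with the higher UMI minimum. Without the 5 highest cells of each library the log2 ratio was 1.32 for Ifng, 0.99 for Areg, which encodes the growth factor amphiregulin, and 2.48 for Gzmd. The Penk ratio was 0.90 with the marker gate and 3.25 with the higher UMI minimum. With only Y-linked Ifnar1-SA cells set against WT it was 0.30 for Penk, 0.05 for Areg and -1.02 for Itga4. The 12 lowest were Itga4, Hist1h2ae, Hist1h2ap, Ier5l, Ppp1r3b, Cdk6, Bcl2, Ccna2, Fgl2, Mri1, Gprin3 and Sema6d. Bcl2, a survival factor, had a log2 ratio of -1.02 (-1.16 to -0.87), Cdk6, a kinase of the G1 phase, -1.04 (-1.19 to -0.89), and Ccna2, the cyclin A2 gene, -1.01 (-1.25 to -0.77), which was -0.42 with the clusters weighted equally. The histone gene Hist1h2ap, at -1.51, was also lower in regulatory T-like (-1.49) and monocyte/macrophage-like cells (-1.02) and in the high-UMI cluster (-1.65).

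**Figure D4:**
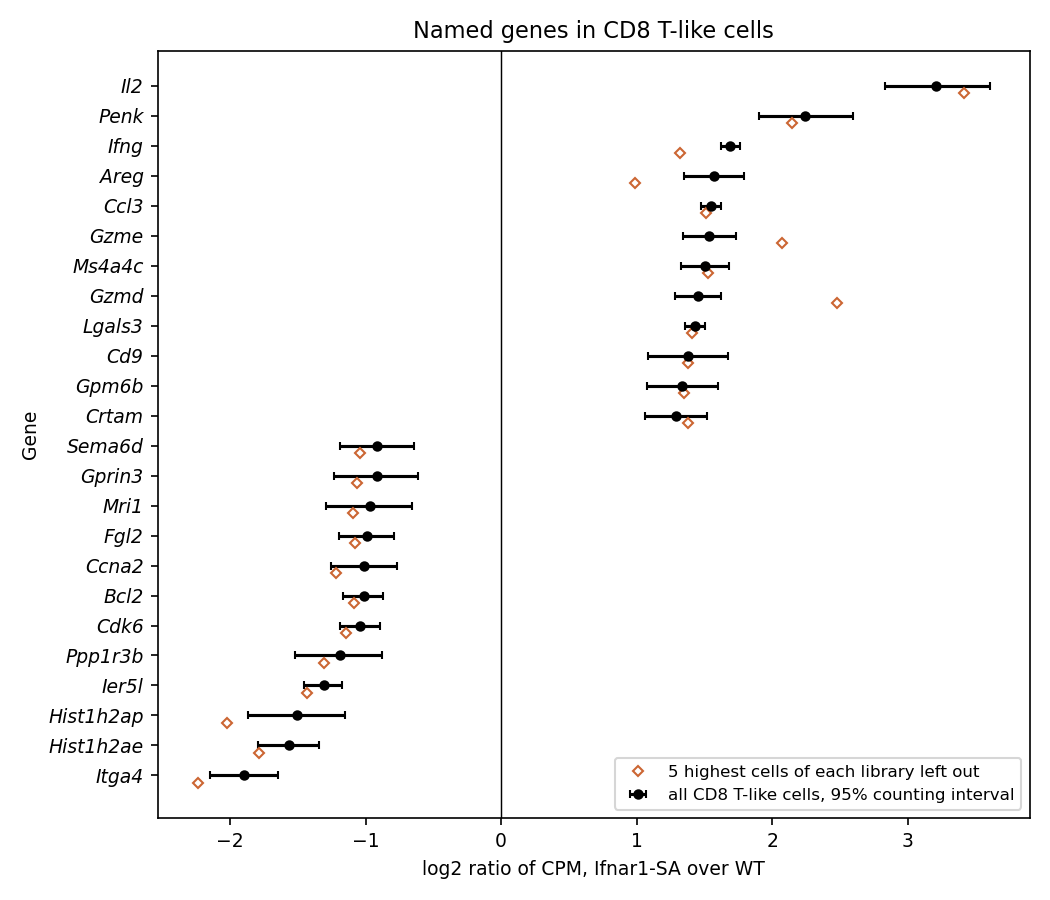
Log2 ratio of CPM (Ifnar1-SA over WT, horizontal axis) of the 12 highest and 12 lowest named genes in CD8 T-like cells. Black points have exact 95% counting intervals and open diamonds leave out the 5 highest cells of each library; Itga4 lies at -1.89, and Ifng moves from 1.69 to 1.32.

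Of 22 measured cytotoxic effector genes 20 were higher, with a median log2 ratio of 0.38 (percentile 100). Gzmk, a granzyme of early memory-like cells, was lower at -1.10 (-1.46 to -0.75). All 24 proliferation genes were lower, with a median of -0.46 (percentile 0), among them Top2a at -0.75 and Mki67 at -0.62. That median was -0.053 when the clusters of the class were weighted equally, and -0.31, -0.20 and -0.014 within clusters 7, 11 and 12. Of 8 naive, stem and memory genes 7 were higher, with a median of 0.48 (percentile 100). They include Ccr7, the lymph node homing receptor, at 0.96 and Bach2, a repressor that restrains effector differentiation, at 1.18, with Bcl2 as the exception. Inhibitory receptor and exhaustion genes went both ways, 14 higher and 7 lower, with a median of 0.14 (percentile 99.5) that turned to -0.035 under the marker gate. Lag3 and Cd160, both inhibitory receptors, had log2 ratios of 0.60 (0.50 to 0.70) and 0.78 (0.64 to 0.92), while Tox, a transcription factor of the exhausted state, had -0.91 (-1.11 to -0.72) and Pdcd1, the PD-1 gene, -0.14 (-0.22 to -0.06).

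With each cell thinned to 2000 UMIs, 25.4% of WT (22.5 to 28.4%) and 34.7% of Ifnar1-SA CD8 T-like cells (30.8 to 38.8%) held an Ifng UMI, and 22.6% and 13.3% a Tox UMI. In monocyte/macrophage-like cells, which should lack both genes, Ifng was found in 0.337% and 0.155% and Tox in 0.0674% and 0.103%. Unthinned, the CD8 T-like shares were 45.9% and 52.0% for Ifng and 47.5% and 27.5% for Tox, at medians of 5920.5 and 5017.5 UMIs per CD8 T-like cell and 10871 and 8776.5 per monocyte/macrophage-like cell. Thinning left out 123 WT and 74 Ifnar1-SA CD8 T-like cells. Among the other genes thinned in CD8 T-like cells, the intervals were also apart for Ccl3, Itga4, Mki67, Top2a and Pdcd1. They overlapped for Gzmb, Prf1, Isg15, Ifit3, Havcr2, Il2, Tcf7 and Cd8a. The share with a Gzmb UMI was 51.7% in WT (48.3 to 55.0%) and 54.6% in Ifnar1-SA (50.4 to 58.7%), but unthinned 64.3% and 60.7%. That with an Isg15 UMI was 19.5% (16.9 to 22.3%) and 24.4% (20.9 to 28.1%).

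The other lists in CD8 T-like cells had medians of 0.09 for interferon gamma leaning genes (10 of 16 higher), 0.14 for interferon receptors and signalling (8 of 12), 0.08 for tissue residency (4 of 7), 0.02 for survival and apoptosis (8 of 13) and 0.02 for MHC class I presentation (10 of 19). MHC class II presentation genes, which mark antigen-presenting cells, had 0.39 (5 of 5 higher, led by Cd74), and inflammatory myeloid genes 0.63 (5 of 5 higher), of which Ccl3, Ccl4 and Ccl5 are also T cell chemokines. The medians were 0.14 for costimulation and checkpoint ligands, 0.27 for suppressive macrophage genes, 0.15 for regulatory T function, -0.07 for hypoxia and glycolysis, -0.16 for sterol genes and 0.13 for dissociation stress. The MHC class II median was 0.19 without cells that held markers of another lineage (3 of 4 higher). With only Y-linked Ifnar1-SA cells set against WT, the median turned to -0.14 for MHC class II, -0.23 for suppressive macrophage and -0.67 for tissue residency genes.

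In regulatory T-like cells genes of the type I interferon list and the effector genes Gzmb and Ccl4 were higher in Ifnar1-SA, while genes of regulatory T function went both ways. Ifit1, which binds viral RNA, had a log2 ratio of 1.71 (1.47 to 1.96), and Gzmb 0.79 (0.74 to 0.83). The chemokine gene Ccl4 was at 218.4 CPM in WT and 746.6 CPM in Ifnar1-SA. Foxp3, the lineage transcription factor, had 0.16 (0.03 to 0.28), Ctla4, an inhibitory receptor, 0.01 (-0.04 to 0.05), and Il10, an anti-inflammatory cytokine gene, 1.04 (0.76 to 1.31). The regulatory T function list had a median of 0.03, with 10 of 16 higher.

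The 5 highest named genes in regulatory T-like cells were Il1b, Ccl2, Ly86, Ms4a4c and Fcer1g, genes mainly of myeloid cells, with log2 ratios from 2.95 to 2.17. The inflammatory myeloid list had a median of 1.26 and the MHC class II list 1.01 in these cells. Without the 18 WT and 75 Ifnar1-SA cells that held at least 10 UMIs of macrophage markers, a split made after the data were seen, the highest genes were Ifi44 (1.82), Ccl4 (1.82), Ifit1 (1.79), Ifi213 (1.76) and Rsad2 (1.74). The lowest were then Hist1h2ae, Mt3, Gadd45gip1, Ifi27, at -0.94 (-1.15 to -0.73), and Itga4, at -0.88. The type I interferon median was then 0.79 and the MHC class II median -0.14. Ifi27 is an interferon-inducible gene outside the type I interferon list, and in all cells of each class it was lower in regulatory T-like (-0.82), other T-like (-0.54), CD8 T-like (-0.41) and monocyte/macrophage-like cells (-0.54). When only Y-linked Ifnar1-SA cells were set against WT, Il1b turned to -0.85, Fcer1g was at 0.04 and Mt3 at -0.21. Ccl2, at 2.48, was at 0.73 with a mitochondrial maximum of 20% and at 0.42 without the cells that held macrophage markers, but at 4.89 with the free RNA profile subtracted. With all cells of the class, the 5 lowest were Mt3, a metallothionein gene, at -1.18 (-1.50 to -0.87), Hist1h2ae, Gadd45gip1, Olfr1369-ps1 and Cystm1. Proliferation genes were lower in 23 of 24 cases with a median of -0.29, and hypoxia and glycolysis genes in 17 of 20 with a median of -0.29, among them Eno1, the enolase gene, at -0.49 and Hk2, a hexokinase gene, at -0.63. Both medians lay at percentile 0. Cluster 5 of this class, with the proliferation gene Mki67 among its leading genes, held 119 of 539 WT and 142 of 807 Ifnar1-SA cells. Make-up of this class and expression within cells were not separated, so the lower proliferation median may in part reflect that make-up. With only the 45 Y-linked Ifnar1-SA cells of this class set against WT, the median was -0.038 for proliferation genes, with 11 higher and 13 lower, and -0.52 for hypoxia and glycolysis genes.

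In other T-like cells the 5 highest named genes in Ifnar1-SA were Oasl2, Usp18, Ifitm1, Lgals7 and Irf7, of which all but Lgals7 are interferon-inducible. Usp18, a negative regulator of interferon receptor signalling, had a log2 ratio of 1.58 (1.05 to 2.13), and Oasl2 1.66 (1.05 to 2.30). Cytotoxic and inhibitory receptor genes were mostly lower. Gzma, a granzyme, was at 928.5 CPM in WT and 311.8 CPM in Ifnar1-SA, Rgs16 had a log2 ratio of -1.23 (-1.57 to -0.90) and Lag3 -0.80 (-1.29 to -0.32). Cytotoxic effector genes were lower in 13 of 18 cases with a median of -0.19 (percentile 0.28), and inhibitory receptor and exhaustion genes in 16 of 20 with a median of -0.27 (percentile 0.01). The median was 0.36 for interferon gamma leaning genes, with 16 of 20 higher. With only the 29 Y-linked Ifnar1-SA cells of this class set against WT, the cytotoxic effector median turned to 0.39, with 10 higher and 7 lower.

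Among the 5 lowest in other T-like cells, Il5, Il13, Il2, Ccl8 and Cd70, the cytokine genes rested on very few cells. All 155 Il5 UMIs lay in 1 WT cell, against 0 UMIs in Ifnar1-SA, and 1 cell held 94.3% of the Il2 UMIs in WT and another 87.1% in Ifnar1-SA. The Il2 ratio of -2.45 turned to 1.71 with a minimum of 2000 UMIs together with a raised gene minimum. Ifitm1, at 1.57, turned to -0.37 with a mitochondrial maximum of 5%. Lgals7, at 1.46, had 62.9% of its Ifnar1-SA UMIs in 1 cell and turned to -0.12 without cells that held markers of another lineage. Cd70, a costimulatory ligand, had -1.90 (-2.52 to -1.33), and -0.92 in thinned cells, and Ccl8, at -2.34, was at -0.78 with minimums of 500 UMIs and 250 genes. Of the red cell genes, Hbb-bs and Hba-a1 had 67 and 62 UMIs in WT other T-like cells and 0 in Ifnar1-SA, and no class compared had enough measured members of that list for a median.

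In monocyte/macrophage-like cells most genes of the type I interferon list were higher in Ifnar1-SA, and most genes of MHC class II presentation and of hypoxia and glycolysis were lower. Slfn4, an interferon-inducible gene of myeloid cells, was the highest named gene, at 80.6 CPM in WT and 184.9 CPM in Ifnar1-SA (log2 ratio 1.20, 1.11 to 1.29), followed by Sh2d1b1, Ms4a4b, Ifi44 and Sirpb1b. H2-Eb1, a class II chain, was at 4969 CPM in WT and 2853 CPM in Ifnar1-SA, and Cd74, the invariant chain that chaperones class II molecules, had a log2 ratio of -0.80 (-0.81 to -0.79). The 5 lowest named genes were F13a1, a coagulation factor XIII chain made by monocytes and macrophages, at -1.83 (-1.98 to -1.68), Chil3 at -1.59 (-1.72 to -1.46), Ccl6, Trf and Folr2. In WT, 5 cells held 34.9% of the Chil3 UMIs. Without the 5 highest cells of each library the Chil3 ratio was -1.12 (-1.27 to -0.98). Mrc1, the macrophage mannose receptor, had -0.96 (-1.04 to -0.88) and Arg1, the arginase gene, -0.83 (-0.88 to -0.77). Cluster 3 of this class, with Folr2 and Arg1 among its leading genes, held 311 of 1523 WT and 325 of 2050 Ifnar1-SA cells. Make-up of this class and expression within cells were not separated.

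Of 8 measured MHC class II genes in monocyte/macrophage-like cells 7 were lower, with a median log2 ratio of -0.49 (percentile 0), and Ctss was the exception at 0.07. All 19 hypoxia and glycolysis genes were lower, with a median of -0.21 (percentile 0), among them Hilpda, a hypoxia-inducible lipid droplet gene, at -0.78 and Eno1 at -0.46. With only Y-linked Ifnar1-SA cells set against WT that median turned to 0.13, with 13 higher and 7 lower. Interferon gamma leaning genes had a median of 0.14, in which Gbp2, a guanylate-binding protein gene, was at 0.20 and Cxcl9, a chemokine gene, at -0.31. Inflammatory myeloid genes were lower in 9 of 14 cases, with a median of -0.07, among them Cd14 at -0.66 and Cxcl2 at -0.63. Suppressive macrophage genes were lower in 9 of 14, with a median of -0.08. Dissociation stress genes were lower in 16 of 21, with a median of -0.12 (percentile 0.01), among them the heat shock genes Hspa1b at -0.56 and Hspa1a at -0.38. Cluster 16 of this class, led by Retnla, Cd163, F13a1 and Lyve1, held 44 WT cells and 1 Ifnar1-SA cell. With that cluster left out, a choice made after the data were seen, the log2 ratio was -0.96 for F13a1 and -0.86 for Ccl6. For F13a1 it was -2.48 both in thinned cells and with every cell weighted equally. With only Y-linked Ifnar1-SA cells set against WT it was 2.02 for Slfn4 and -1.97 for Trf.

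The high-UMI cluster, with medians of 50884 UMIs in WT and 50904 in Ifnar1-SA, was led by Sdc2, Dcn, Cd34, Rhox5 and Tm4sf1 and stayed unnamed. Neither Xist nor a Y-linked gene was found in 165 of its 183 WT and 171 of its 191 Ifnar1-SA cells. In WT CD8 T-like cells, which are shallower, that held for 28 of 994. The cluster may therefore not be cells of the mice, and whether it carries the Ifnar1-SA allele is not known. Whether it comes from the inoculated MC38 cells was not tested. Most interferon-inducible genes of this cluster were lower in Ifnar1-SA. Cxcl9 and Cxcl10, chemokine genes induced by interferon, were at 654.3 and 1170 CPM in WT and at 234.5 and 555.9 CPM in Ifnar1-SA, and Isg15 had a log2 ratio of -0.47 (-0.53 to -0.42). The type I interferon list had a median of -0.20, with 34 of 40 members lower, and the interferon gamma leaning list -0.38, with 16 of 16 lower; both lay at percentile 0. The 5 lowest named genes were Col1a1, a collagen chain gene, at -2.44 (-2.66 to -2.23), Hist1h2ae, Bgn, Mfap4 and Ccl5. The UMIs of Mfap4, a microfibril gene, lay in 31 WT and 20 Ifnar1-SA cells, and 5 cells held 44.3% and 77.1% of them. Only Cd74, Fcer1g and Fabp5 passed the rule as higher. Cd74 and Fcer1g are mainly genes of myeloid cells, and 5 cells held 66.6% of Cd74 UMIs in WT and 70.4% in Ifnar1-SA. MHC class II genes had a median of 1.05 and proliferation genes -0.29 in this cluster.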

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

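All tests in this part rest on clusters found in these data, so none was planned before the data were examined. Only the predictions on chance doublets and on CD8 T cells held in mixed droplets were written before those tests were run. Each paragraph compares 1 library with 1 library, and genotype, animals and library preparation follow the same split.

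The type I interferon list was higher in Ifnar1-SA in the 4 named classes compared and lower in the high-UMI cluster, at a median log2 ratio of -0.20. The difference between classes was not tested, and the high-UMI cluster largely lacked sex-linked transcripts and may not carry the allele. A shift of these genes over the whole library is argued against by that -0.20, which has the opposite sign. Myeloid RNA in T cell droplets is argued against as the cause in regulatory T-like cells, since the median there was 0.79 without cells holding at least 10 macrophage marker UMIs. In the same class the median was 0.74 among cells with Xist and no Y-linked transcript. Only 45 of its 807 Ifnar1-SA cells held Y-linked transcripts alone, so leaving them out could hardly have lowered the median. The split shows only that Y-linked cells do not carry the difference in this class, and it does not cover the other classes. What stays open is whether the higher Irf7, Isg15 and Rsad2 belong to the Ifnar1 allele, to the animals or to the handling of 1 library; that the allele may be the cause is an untested hypothesis.

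Droplets with T cell and macrophage transcripts were 10.1% of kept cells in Ifnar1-SA, a cluster outside the comparisons, against 3.03% in WT. Chance doublets are argued against as the whole cause: pairs of T and macrophage markers in Ifnar1-SA were 3.93 times as frequent (2.75 to 5.83) as pairs of either with the high-UMI cluster imply, and in WT 2.13 times (1.48 to 3.16). Joining of cells within 1 animal before pooling is argued against as the only source, since 15.8% of these droplets with sex-linked transcripts held both Xist and a Y-linked gene, above 6.28% in monocyte/macrophage-like cells, though below 20.6% for simulated random pairs. Joining after animals were pooled, such as T cells sticking to macrophages in suspension, may contribute and was not tested, and no biological explanation was tested.

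The CD8 T-like share was lower in Ifnar1-SA. CD8 T cells held in mixed droplets are argued against as the whole cause by number alone, since mixed droplets were 3.03% of WT and 10.1% of Ifnar1-SA cells. The difference was -10.8 points with mixed droplets that carried Cd8a or Cd8b1 and no Foxp3 added. Given those shares the outcome could not have favoured this explanation, so it is not an independent test. Animals that differ within the Ifnar1-SA library may contribute: there were 2.93 CD8 T-like per regulatory T-like cell among cells with Y-linked transcripts, against 0.606 among cells with Xist only and 1.84 in WT. The sex of the animals and differences between single animals were not separated by this test, and an effect of the allele stays open and untested.

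Y-linked genes had 1226 UMIs in Ifnar1-SA and 4 in WT, a signal outside the comparisons. Il2 had opposite log2 ratios in CD8 T-like cells (3.21) and other T-like cells (-2.45), a difference that was not tested and rests on few cells. The cytotoxic effector list was lower in other T-like cells, at a median of -0.19, and higher in CD8 T-like cells, at 0.38, but the other T-like median was 0.39 with only the 29 Y-linked Ifnar1-SA cells set against WT. The inhibitory receptor and exhaustion list had a median of -0.27 in other T-like cells, while in CD8 T-like cells 14 genes were higher and 7 lower, with a median of 0.14 that was -0.035 under the marker gate. These differences were not tested either.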

How the results depend on the processing

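The alternatives on sex-linked transcripts, on cells with markers of another lineage, on equal weighting of CD8 T-like clusters, on clusters of 1 library and on tied doublet scores were chosen after the results were seen. With 1 library per group no replicate could be left out, and no paired analysis was possible because each group has 1 library. Of 198 values of the 11 main results under alternatives, 193 kept their direction, 27 of these beyond the main interval. Of 947 values of the 53 named genes, 941 kept their direction, 236 of these beyond the main interval, and 104 values differed from the main one by more than 1.5-fold. Where values moved or turned, the cause was not tested. With barcodes of tied doublet scores kept in, each of the 11 main results stayed within its main interval. Another scaling moved the median of all genes by at most -0.054 on the log2 scale. The free RNA share was estimated at 1.72% of CD8 T-like UMIs in WT and 2.04% in Ifnar1-SA. Depth limits genes under 20 CPM, the dendritic cell-like classes and single genes in other T-like cells.

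With Y-linked Ifnar1-SA cells against WT, the share difference was -0.37 points for CD8 T-like, -5.26 for regulatory T-like and 13.5 for monocyte/macrophage-like cells, and with Xist-only cells it was -14.2, 6.50 and -1.16. With the order-of-magnitude UMI minimum (8030.0 in WT and 7951 in Ifnar1-SA) these were -9.30, -0.56 and -2.76 points, and the marker gate gave -5.84 for CD8 T-like cells. The proliferation median in CD8 T-like cells was -0.053 with clusters weighted equally and -0.30 with Y-linked cells. It was -0.41 with a minimum of 2000 UMIs together with a raised gene minimum. With cells weighted equally it was -0.40, with the marker gate -0.71 and with the order-of-magnitude minimum -0.41.

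The type I interferon median in CD8 T-like cells was 0.36 with clusters weighted equally and 0.36 with Leiden resolution 2. It was 0.26 with Y-linked cells, 0.17 with Xist-only cells and 0.39 with the marker gate. It was 0.14 with a minimum of 2000 UMIs together with a raised gene minimum. With mitochondrial maxima of 20% and 5% it was 0.17 and 0.38, and with the order-of-magnitude minimum 0.38. In monocyte/macrophage-like cells the type I interferon median was 0.33 with TMM and 0.32 with median-of-ratios scaling. In other T-like cells it was 0.32 with Y-linked cells and 0.36 in thinned cells. In regulatory T-like cells it was 0.63 with Y-linked cells and 0.64 with the order-of-magnitude minimum.

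The inhibitory receptor and exhaustion median in CD8 T-like cells turned from 0.14 to -0.035 with the marker gate. Named genes that turned included Il2 with a minimum of 2000 UMIs together with a raised gene minimum. Its ratio was then -0.47 in CD8 T-like cells and 1.71 in other T-like cells. In CD8 T-like cells Il2 also turned with the order-of-magnitude minimum (-2.84). The others were Ifitm1 (-0.37 with a mitochondrial maximum of 5%) and Lgals7 (-0.12 without cross-lineage cells) in other T-like cells, and Il1b in regulatory T-like cells (-0.85 with Y-linked cells).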

Other observations

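The values in this part were chosen after they were seen, from comparisons over all genes and lists. In the cluster of mixed T and macrophage droplets, genes of regulatory T cells were higher in Ifnar1-SA: Foxp3 had a log2 ratio of 1.07 (0.61 to 1.56) and Ctla4 0.93 (0.75 to 1.11), and 11 of 13 genes of regulatory T function were higher with a median of 0.46, while Cd8a had -0.14 (-0.52 to 0.25). MHC class II genes of this cluster were lower in 7 of 8 cases with a median of -0.65, and type I interferon genes higher in 50 of 52 with a median of 0.56. The gene Mcpt2, a mast cell protease that leads this cluster, had 656 UMIs in 1 WT cell.

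Few genes had a counting interval wholly past 1.5-fold in one direction in at least 4 groups among the named classes and the high-UMI cluster. Shared shifts short of that rule, such as those of Irf7 and Ifi27 in the named classes, are not counted here. Ccl8, a monocyte-attracting chemokine gene most abundant in monocyte/macrophage-like cells, was lower in Ifnar1-SA in the 4 named classes compared and in the high-UMI cluster, with log2 ratios from -0.70 in monocyte/macrophage-like cells to -2.49 in the high-UMI cluster. In WT it stood at 1779 CPM in monocyte/macrophage-like cells but at 31.5 CPM in CD8 T-like cells, where free RNA was estimated at 1.72% of UMIs. Its values outside monocyte/macrophage-like cells may thus in part reflect free RNA. The histone gene Hist1h2ap was lower in the same groups, from -1.02 in monocyte/macrophage-like to -2.83 in other T-like cells, where it had only 5.17 CPM in WT. The predicted gene Gm10076 was lower in them too, from -0.77 to -1.20, and Gm47283 was lower in the named classes, from -1.38 in CD8 T-like to -2.69 in regulatory T-like cells, but not in the high-UMI cluster (0.13). Ly6c2, which encodes a surface protein of inflammatory monocytes and activated T cells, was higher in the named classes, from 0.60 in other T-like to 1.73 in regulatory T-like cells. In the high-UMI cluster it was at 1.81, with only 3.15 CPM in WT and 11.0 CPM in Ifnar1-SA. It met the rule in 4 groups, so not in every group given here. In WT it stood at 679.0 CPM in monocyte/macrophage-like but at 35.6 CPM in regulatory T-like cells. Its ratio in regulatory T-like cells may thus in part reflect myeloid RNA, which was not tested. Eno1, the enolase gene, did not meet that rule but was lower in the named classes and in the high-UMI cluster. The median of its list, hypoxia and glycolysis, was -0.29 in regulatory T-like cells, but the medians of -0.07 in CD8 T-like and -0.15 in other T-like cells lay inside the central 95% of random matched lists (-0.10 to 0.11 in CD8 T-like cells), and with only Y-linked Ifnar1-SA cells set against WT the median was 0.13 in both monocyte/macrophage-like and other T-like cells.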
